A study of Oryza sativa Indica Group with 14 samples.

How the data were processed

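The series covers 14 samples of rice anthers of an indica cultivar at a leptotene-like stage, which per the labels' protocols was judged by floret length. Per the labels, the mutant came from plants treated with gamma rays, and wild-type and mutant plants were offspring of a heterozygote. Each sample pooled anthers of 3 plants, and plants grew at 1 of 2 field sites, with no site given for a sample. Small RNA was sequenced from 3 wild-type and 3 mutant samples, mRNA from 2 and 2, and bisulfite-treated DNA from 2 and 2. Per the labels, total RNA prepared for small RNA sequencing also served for mRNA sequencing. Groups and replicate numbers were taken from the sample titles. The third mutant small RNA sample is labeled mRNA in its molecule subtype, against its title and source name, and was kept as small RNA. The submitters' processing notes name cutadapt, bedtools, HISAT2, featureCounts, DESeq2, Bismark and methylKit, with no version and no role. The genome build, the caller of phased loci, library totals and coverage minimums were not given in the sources used here.

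For mRNA the authors deposited FPKM values (fragments scaled by gene length and library size) of 55801 loci in each of 4 libraries, with identifiers of the LOC_Os form. All 39873 loci above 0 in any library had values that were whole multiples of 1 fragment in all 4 libraries (100% within 0.0001 fragments). Other multiples of a base total left 99.98% or more of loci whole too. The multiple was therefore chosen by how close the recovered fragments summed to the total, 98.05% against 73.77% to 192.14% at the others. Inferred library totals were 28815932 and 27236316 fragments for wild-type replicates 1 and 2 and 29690786 and 27519542 for mutant replicates 1 and 2. Each locus took the shortest length that fitted, so its recovered fragments are the fewest that fit. Over the genes with a mean of at least 1 FPKM the median was 514 to 585 fragments in 1 library. For small RNA the authors deposited 1 list of 21-nt and 1 list of 24-nt PHAS loci per library, with coordinates and a phase score. Whether the score was scaled by library size was not given in the sources used here. A score was used to rank loci, to count them at a threshold and to compare medians for their direction. For methylation the authors' deposited table gives, for windows of 100 bp in each of the contexts CG, CHG and CHH, a difference in percentage points with its p-value and q-value. The step between windows was 50 bp for CG and CHG and 30 bp for CHH. That table compares the genotypes and holds no values or coverage per library, and the sign convention was not given in the sources used here.

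Genes with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 (R 4.3.3, eBayes with trend) on log2(FPKM + 1), with genotype as the only term. A call is a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and the direction is mutant minus wild type. Lists of genes were written before the data were examined, from general knowledge. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with adjustment over the 11 lists that had tested members. Reported beside these are calls over all genes and calls adjusted over the list alone. Photosynthesis genes, genes of palea, lemma, lodicule and carpel identity and later pollen genes were included as markers of other tissues or stages. *MEL1* stands in 2 lists, and anthers express low levels of some photosynthesis genes. Pairs of symbol and identifier were checked against a table of rice genes on the assembly ASM3414082v1. It held 63 of the 106 symbols, 61 of them on the chromosome of the identifier, and 194 of 194 pairs compared stood in the same order. The 2 symbols found only on another chromosome, *DMC1B* and *ZIP4*, were left out. Counting by strand and the handling of reads shared by paralogs were not given in the sources used here, so values of close paralogs and of overlapping genes are uncertain. The test was tried on simulated data for 20232 genes of the mutant and wild-type mRNA comparison. It recovered 90 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 13 false calls.

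Genes were named by a rule fixed before the data were examined: *OsRDR6*, all measured members of the DSB list, up to 3 members of each other list with the smallest p, and the genes with the largest changes among those past the threshold with a mean of at least 5 FPKM and no overlap between genotypes. Of the last kind only 2 per direction are printed, since nothing used here pairs them with names. PHAS loci were named by the highest mean score over the 3 libraries, 3 per size and direction, and methylation windows by the lowest q.

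PHAS loci were merged over the 6 libraries where they overlapped by at least 1 bp. Numbers per library and median scores were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Loci found in all libraries of 1 genotype and none of the other were counted in the real split and in the 9 other splits. On simulated data for these sets of loci, 60 of 60 planted wild-type loci and 30 of 30 planted mutant loci were recovered. Each was planted in all 3 libraries of its genotype, so this tried the merging and not how many members of a set are false. Counting error could not be computed for loci because library totals were not given in the sources used here.

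Differential windows of the authors' deposited table are those with q below 0.01 and a difference of at least 25 points for CG and CHG or 10 points for CHH. They were counted by direction, by chromosome and in bins of 1000000 bp holding at least 2000 windows. Windows overlapping PHAS loci found in all 3 libraries of either genotype were compared with 1000 circular shifts of the loci along their chromosomes, two-sided, where the smallest p is 0.002, with adjustment over 6 tests. As a trial, 200 loci were placed at differential windows of the authors' deposited table among other 24-nt loci. The CG, CHG and CHH tests of windows at PHAS loci each gave a permutation p of 0.01, the smallest possible with the 200 shifts used here. The loci were planted on windows already past the thresholds, and the other loci stood at their real places. A low p was therefore all but fixed, and the trial does not measure how small an excess the tests would find. Of 40 sets of 21-nt loci moved at random, 2, 0 and 0 fell below 0.05. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 for the plots.

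Alternatives for mRNA were a pseudocount of 0.1, no filter or a filter of 5 FPKM, quantile or median-ratio scaling, limma without trend, the replicate number as a block, a fold change minimum and each library left out. For loci they were the stronger part of all loci by median score, merging, padding by 100 bp, an overlap of 50% and each library left out, and for windows other limits of q and difference, merged regions and non-overlapping windows. The limma voom fit on recovered fragments, the thresholds on phase score and the lists with both left-out pairs kept were added after the data were seen. Expression of genes at PHAS loci or differential windows was planned and left out, because no gene coordinates of a build known to be that of the files were used here. A limit on coverage and a fit leaving out bisulfite libraries were left out as well, since the table holds no values per library.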

Results

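Anthers of rice at a leptotene-like stage, when meiotic chromosomes begin to condense, were compared between wild type and *Osrdr6-mei*, a mutant of OsRDR6. OsRDR6 is an RNA-dependent RNA polymerase. Such enzymes turn cleaved transcripts into double-stranded RNA, which Dicer proteins cut into phased small RNAs (21-nt or 24-nt) at sites known as PHAS loci. The series asks what this enzyme contributes to the DNA double-strand breaks (DSBs) that start meiotic recombination. Its 14 samples held small RNA libraries from 3 wild-type and 3 mutant samples, mRNA libraries from 2 and 2, and bisulfite libraries from 2 and 2. Each sample pooled anthers of 3 plants. The mRNA libraries held 27236316 to 29690786 fragments, as inferred from the FPKM values. The depth of the small RNA and bisulfite libraries was not given in the sources used here.

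The transcript of the mutated gene itself was not lower in the mutant. *OsRDR6* (LOC_Os01g34350) stood at 22.5 ± 0.30 FPKM in wild type and 33.4 ± 1.54 FPKM in the mutant (SD, n = 2), a log2 fold change of 0.55 (SE 0.12). It did not pass the threshold in limma (adjusted p = 0.0644). The nature of the allele was not given in the sources used here, so this transcript level does not test the genotype labels.

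Of 20232 genes tested, 250 rose and 389 fell in the mutant in limma at a Benjamini-Hochberg adjusted p below 0.05. Among them the argonaute gene *AGO18* (LOC_Os07g28850) fell from 58.0 ± 4.21 to 7.76 ± 0.43 FPKM (log2 fold change -2.75, SE 0.13, limma adjusted p = 0.00031, n = 2), or 7.47-fold. *MEL1* (LOC_Os03g58600), a germline argonaute gene of early meiocytes, rose from 78.6 ± 1.84 to 170 ± 23.9 FPKM (log2 fold change 1.09, limma adjusted p = 0.0127, n = 2). The largest increases belonged to LOC_Os12g14310 and LOC_Os12g39470. In recovered fragments the first had 4 and 4 in wild type against 225 and 290 in the mutant, and the second 7 and 6 against 328 and 445. Their log2 fold changes were 4.87 and 4.44. The largest decreases belonged to LOC_Os01g04090 (-3.53) and LOC_Os02g32190 (-3.44), whose wild-type replicates differed widely, at 40.3 and 7.10 FPKM and at 31.8 and 8.22 FPKM. They lost their calls in 6 and 3 of 12 alternatives (adjusted p 0.00362 to 0.245 and 0.00362 to 0.199). The sources used here do not pair these 4 identifiers with names. Values of the genotypes did not overlap at 50.7% of tested genes, where chance gives 33.3% for 2 against 2 libraries. The counts moved by over 1.5 times when 1 library was left out: to 232 lower without mutant replicate 1, 102 higher and 183 lower without mutant replicate 2, 242 lower without wild-type replicate 1, and 95 higher without wild-type replicate 2. Without a filter on low values, when 39873 genes entered both the fit and the adjustment, 17 rose and 85 fell.

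Among genes needed for meiotic DSB formation, *SDS* (LOC_Os03g12414), a cyclin gene, fell. It stood at 14.2 ± 0.008 FPKM in wild type and 4.53 ± 0.12 FPKM in the mutant (log2 fold change -1.46, SE 0.14, limma adjusted p = 0.00338, n = 2). The other 4 members did not pass the threshold over all genes. *CRC1*, which also acts in the synaptonemal complex, had a log2 fold change of -0.85 (limma adjusted p = 0.0727), and *SPO11-1*, a subunit of the enzyme that cuts DNA, had -0.40 (adjusted p = 0.169). *MTOPVIB*, its partner subunit, had 0.12 and *PAIR1* had 0.08. Adjusted over the list alone, 3 members were lower and 0 higher. The list of 5 genes fell as a set (camera adjusted p = 0.00866, median log2 fold change -0.40), and this call was lost with an estimated correlation (adjusted p = 0.272). The test fry, which asks whether a list moves on balance 1 way, gave an adjusted p of 0.00787. In the same libraries photosynthesis genes, markers of green floret tissue, were higher in the mutant by a median of 1.10 on the log2 scale.

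Genes of meiotic entry, the chromosome axis and the synaptonemal complex went both ways. *ZEP1*, the transverse filament of the synaptonemal complex, fell from 85.3 ± 3.84 to 37.4 ± 2.35 FPKM (log2 fold change -1.17, limma adjusted p = 0.00421, n = 2). *PAIR2*, an axis gene, fell by 0.92 on the log2 scale (adjusted p = 0.0273) and was picked after its value was seen. *MEL1* and *MEL2*, which act at meiotic entry, rose, *MEL2* by 0.82 (adjusted p = 0.022). The list of 9 genes had a median of -0.19 and a mean of 0.01, and camera placed it down without passing (adjusted p = 0.642). Adjusted over the list alone, 3 members were higher and 2 lower. The calls of *MEL1* and *MEL2* were lost without mutant replicate 1 and without wild-type replicate 2. Those of *MEL2* and *PAIR2* were each lost in all 4 fits that left out 1 library, and over all 12 alternatives the adjusted p ran from 0.0167 to 0.0999 for *MEL2* and from 0.0197 to 0.182 for *PAIR2*.

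Genes of meiotic recombination and crossover had 0 of 7 members past the threshold in limma over all genes tested. *DMC1A*, a recombinase gene, had a log2 fold change of 0.63 (limma adjusted p = 0.0823), the crossover genes *MSH4* and *HEI10* had -0.43 and -0.39. Adjusted over the list alone, 1 member was higher and 3 lower, and camera did not call the list (adjusted p = 0.128).

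The genes thought to be controlled by tasiR-ARF, small RNAs whose making needs RDR6, were higher in the mutant as a set. *ARF15* had a log2 fold change of 0.56, *ARF14* 0.61, *ARF3* 0.47 and *ARF2* 0.45, and *ARF2* was named after its value was seen. None of the 4 passed the threshold over all genes in limma (lowest adjusted p = 0.0916), and 4 of 4 were higher when adjusted over the list alone. Camera gave an adjusted p of 0.00866 for the list, fry gave 0.022, and the call was lost with an estimated correlation (adjusted p = 0.272). Photosynthesis genes moved the same way in these libraries, with a median of 1.10.

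Most of the other small RNA genes stayed below the threshold. Of 21 small RNA machinery genes, 1 rose (*MEL1*) and 1 fell (*AGO18*), and the same 2 were called when adjusted over the list alone. *AGO1d* had a log2 fold change of 0.62 (limma adjusted p = 0.119). Camera did not call this list (adjusted p = 0.751). Of 14 DNA methylation genes, limma called 0 over all genes and 0 adjusted over the list alone. Here *ROS1d*, a demethylase gene, had the lowest unadjusted p (0.0615, log2 fold change -0.27). *DRM2* had 0.27 and *DDM1b* 0.24 (camera adjusted p = 0.634).

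Of 5 tested genes of the late tapetum and pollen wall, *C6*, a lipid transfer protein gene, fell from 10.3 ± 0.68 to 4.85 ± 0.13 FPKM (log2 fold change -0.95, limma adjusted p = 0.027, n = 2). *CYP704B2*, an enzyme of pollen wall lipids, had -0.53 and *CYP703A3* had -0.24. All 5 had negative fold changes and camera called the list down (adjusted p = 0.00866, median -0.24), a call lost with an estimated correlation (adjusted p = 0.272) and, with the preset one, without a filter on low values, without mutant replicate 1 or without wild-type replicate 2. In the same libraries 2 lists that mark floret tissue other than the anther were higher. Medians were 1.10 for photosynthesis genes and 1.05 for genes of palea, lemma, lodicule and carpel identity. Over 12 alternatives the adjusted p of this list ran from 0.00244 to 0.076. Adjusted over the list alone, 2 were lower. *C6* lost its call in each of the 4 fits that left out 1 library. Of 8 tested genes of the anther wall and tapetum, none passed in limma over all genes, and adjusted over the list alone 1 was higher and 2 lower. *MIL1* had a log2 fold change of 0.64, *TDR* -0.62 and *TDL1A* -0.60. This list had a median of 0.10 while camera pointed down (adjusted p = 0.634), and the median fell below 0 without mutant replicate 1 or without wild-type replicate 1. The 4 genes of later pollen lay below a mean of 1 FPKM and were not tested.

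Photosynthesis genes, which mark green floret tissue, were higher in the mutant as a set. A small-subunit gene of RuBisCO (LOC_Os12g19381) rose from 3.21 ± 1.02 to 8.76 ± 2.04 FPKM (log2 fold change 1.22, limma adjusted p = 0.0496, n = 2). *PSBO* had 1.29 and a light-harvesting gene (LOC_Os11g13890) had 0.98. Of 10 tested members 1 passed over all genes and 7 were higher adjusted over the list alone (camera adjusted p = 0.000411). This call was lost with an estimated correlation (adjusted p = 0.497), and the wild-type replicates differed between themselves by a median of -1.11 (replicate 2 minus replicate 1). The RuBisCO gene kept its call in 1 of 12 alternatives, and without wild-type replicate 1 *PSBO* and the light-harvesting gene were called but the RuBisCO gene was not.

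Genes of palea, lemma, lodicule and carpel identity were higher as well. *MADS21*, an ovule gene, rose from 0.52 ± 0.08 to 2.26 ± 0.27 FPKM (log2 fold change 1.10, limma adjusted p = 0.0372, n = 2), *MADS6* had 1.30 and *MADS1* had 0.89. The other members, named after their values were seen, were *MADS13* at 1.27, *DL* at 1.05, *MADS15* at 0.38 and *MADS14* at 0.08. Of 7 members 1 passed over all genes and 5 were higher adjusted over the list alone. Camera called the list up (adjusted p = 0.00757), a call lost with an estimated correlation (adjusted p = 0.272). *MADS21* lost its call in each of the 4 fits that left out 1 library. Stamen identity genes gave 0 calls of 5 in limma over all genes, with a median of 0.14 that turned to -0.07 without mutant replicate 2 (camera adjusted p = 0.539). None of these 5 passed when adjusted over the list alone, and *MADS4* had 0.32, *MADS58* 0.33 and *MADS2* 0.14.

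**Figure D1:**
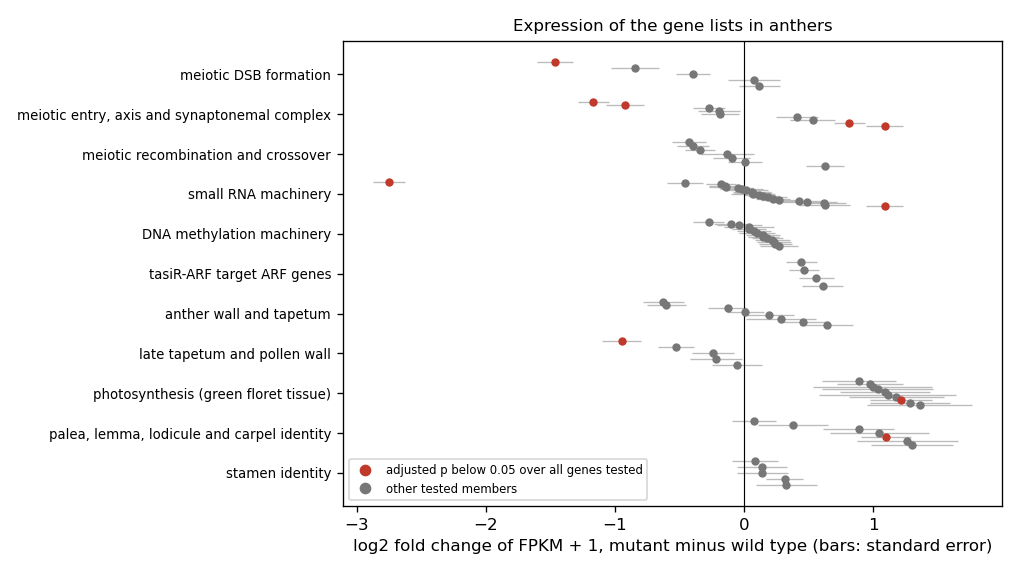
Each point is a tested gene of 1 list, placed by its log2 fold change of FPKM + 1 (mutant minus wild type), with bars for the standard error of limma. Red points passed an adjusted p below 0.05 over all 20232 genes tested, such as *AGO18* at -2.75 and *SDS* at -1.46.

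Strong 21-nt PHAS loci were fewer in the mutant, and shared loci scored lower. Loci with a phase score of at least 25, as the authors scored them, numbered 166 ± 22.5 per wild-type library and 81.3 ± 3.06 per mutant library (SD, n = 3, exact two-sided permutation p = 0.1). At a score of at least 100, the numbers were 126 ± 18.8 and 28.7 ± 4.93, a 4.41-fold difference with every mutant library below every wild-type library (n = 3, exact two-sided permutation p = 0.1). With 3 against 3 libraries, 0.1 is the smallest p possible. The total number of 21-nt loci overlapped between genotypes, at 714 ± 116 in wild type and 626 ± 49.3 in the mutant (n = 3, exact two-sided permutation p = 0.3). At the 25 loci found in all 6 libraries, the median phase score was 287 ± 66.1 in wild type and 36.7 ± 9.15 in the mutant (n = 3, exact two-sided permutation p = 0.1). How the score is defined was not given in the sources used here, so the medians show a direction only.

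Of 2699 merged 21-nt loci, 93 were found in all 3 wild-type libraries and no mutant library, and 51 in all 3 mutant libraries and no wild-type library. Of the 93 wild-type loci 35 had a mean score of at least 25, and of the 51 mutant loci 19, with medians of the mean scores of 5.67 and 11.07. Built from loci with a score of at least 25 alone, the sets held 65 and 17. The wild-type loci with the highest mean scores lay on chromosome 1 (2334706 to 2335546, mean score 723 ± 34.9, n = 3), chromosome 6 (9668416 to 9670650, 647 ± 9.47, n = 3) and chromosome 5 (24911918 to 24912894, 609 ± 45.0, n = 3). Those of the mutant lay on chromosome 12 (21817102 to 21817766, 396 ± 21, n = 3), chromosome 11 (16531035 to 16532004, 237 ± 37.6, n = 3) and chromosome 5 (24851981 to 24852883, 138 ± 18.5, n = 3). Coordinates are those of the deposited lists, whose genome build was not given in the sources used here, so no gene annotation was placed on them. Of other loci found in all 3 wild-type libraries, 27 were found in 1 mutant library, 31 in 2 and 25 in 3. Among 326 loci that reached a score of 25 in any library, every mutant score lay below every wild-type score at 100 and above at 23. A library without a call counted as a score of 0. Only the 103 loci found in all 3 wild-type libraries could therefore count as below, and the 55 found in all 3 mutant libraries as above. Of the 100 loci, 36 had no mutant call, so these counts in part restate where loci were found. Both directions together, the other splits of the libraries gave 2 to 7 loci. Requiring 2 libraries of a genotype in place of 3 raised the wild-type set to 147, 153 and 189 loci without wild-type replicates 3, 2 and 1, and the mutant set to 92, 92 and 106 without mutant replicates 3, 2 and 1.

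For 24-nt PHAS loci the mutant libraries held more loci in total but fewer strong ones. They numbered 38087 ± 9445 per wild-type library and 62030 ± 11246 per mutant library, 1.63-fold more (SD, n = 3, exact two-sided permutation p = 0.1). At a score of at least 10 the genotypes overlapped, with 296 ± 31.5 loci in wild type and 444 ± 123 in the mutant (n = 3, exact two-sided permutation p = 0.2). At a score of at least 25, wild type held 180 ± 14.2 and the mutant 86.3 ± 17.6 loci, and at a score of at least 100 they held 72.7 ± 11 and 19.3 ± 5.51 (n = 3, exact two-sided permutation p = 0.1 for each). The median score over the 9928 loci in all 6 libraries was 0.43 ± 0.06 in wild type and 1.23 ± 0.21 in the mutant (n = 3, exact two-sided permutation p = 0.1). Among 288 loci that reached a score of 25 in any library, every mutant score lay below every wild-type score at 147 and above at 70. Here too a library without a call counted as 0. Only the 242 loci found in all 3 wild-type libraries could count as below, and the 153 found in all 3 mutant libraries as above. Of the 147 loci, 45 had no mutant call.

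Of 97937 merged 24-nt loci, 381 were found in all 3 wild-type and no mutant libraries and 4070 in all 3 mutant and no wild-type libraries. The 3 wild-type loci with the highest mean scores lay on chromosome 10 (11842633 to 11844083, 1807 ± 79.5, n = 3), chromosome 6 (25516554 to 25517707, 1258 ± 121, n = 3) and chromosome 4 (16016489 to 16017312, 1054 ± 198, n = 3). Those of the mutant scored far lower, at 109 ± 30.7 on chromosome 12 (21105012 to 21110363, n = 3), 15.5 ± 1.47 on chromosome 2 (34874688 to 34876159, n = 3) and 11.2 ± 5.84 on chromosome 6 (2838631 to 2839424, n = 3). Of the 4070 mutant loci, 1 had a mean score of at least 25, against 43 of the 381 wild-type loci. The size of both sets moved by over 1.5 times when 1 library was left out. The wild-type set then held 650, 788 and 1011 loci without wild-type replicates 3, 2 and 1, and 805, 897 and 669 without mutant replicates 3, 2 and 1, and the mutant set 6907 without wild-type replicate 3, and 7982, 6207 and 9728 without mutant replicates 3, 2 and 1.

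**Figure D2:**
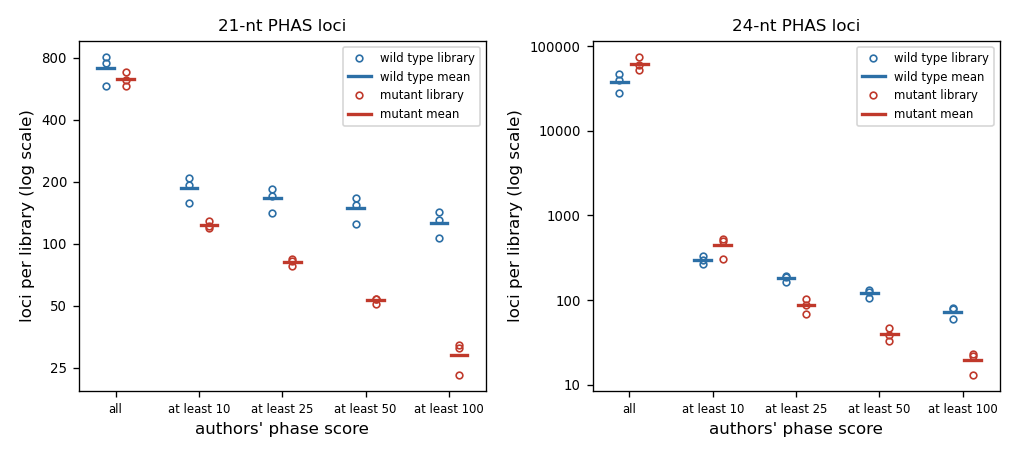
Open circles give the number of PHAS loci in each of the 3 wild-type (blue) and 3 mutant (red) small RNA libraries, counted at rising thresholds of the authors' phase score, on a log axis; bars are means. At a score of at least 100 the means were 126 and 28.7 for 21-nt loci and 72.7 and 19.3 for 24-nt loci, while all 24-nt loci numbered 38087 and 62030.

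Differences in DNA methylation leaned to 1 direction most clearly in the CHH context, where H stands for A, C or T. In the authors' deposited table, 29655 CHH windows of 100 bp had a positive difference past the thresholds and 10573 a negative one, 73.7% positive. Numbers of windows do not rank the contexts, since the limit was 10 points for CHH and 25 for CG and CHG: at 25 points the authors' deposited table held 2457 CHH windows against 10035 for CG and 4918 for CHG. CG windows split more evenly in the authors' deposited table, with 5467 positive and 4568 negative, as did CHG windows with 2751 and 2167. The sources used here do not say which genotype was subtracted from which, so a positive value names no genotype. Mean differences over all windows of the authors' deposited table were 0.32 percentage points for CG, 0.30 for CHG and 0.24 for CHH, and medians were 0.00, 0.00 and 0.07. The chloroplast and the mitochondrion held 0 windows past the thresholds in any context of the authors' deposited table.

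CG windows past the thresholds gathered on chromosome 1. In the authors' deposited table they made up 6.88 per 1000 windows there and 2.14 to 3.42 per 1000 on the other chromosomes. Between 11000001 and 23000000 on chromosome 1, a stretch chosen after the values were seen, the rate in bins of 1000000 bp ran from 12.3 to 30.2 per 1000 CG windows of the authors' deposited table, against at most 8.12 in any such bin of another chromosome. The windows with the lowest q in the authors' deposited table lay there too, such as a CG window at 19453601 to 19453700 with a difference of 81.9 points (q = 2.05e-71) and a CHG window at 19600701 to 19600800 with 75.9 points (q = 2.72e-121). Negative ones in the authors' deposited table were a CHG window at 19534851 to 19534950 of chromosome 1 (-74.1 points, q = 4.96e-46) and a CG window at 18715251 to 18715350 of chromosome 10 (-67.5 points, q = 9.76e-57). For CHH, the authors' deposited table had its lowest q on chromosome 12 at 1574941 to 1575040 (11.3 points, q = 2.12e-69) and on chromosome 7 at 24124591 to 24124690 (-32.3 points, q = 2.9e-100). Chromosome 1 did not stand out for CHH, with 6.04 windows per 1000 in the authors' deposited table against 5.06 to 7.12 elsewhere. All these q values are the authors'. With 2 bisulfite libraries per genotype and no values per library, the spread between libraries could not be set beside them.

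**Figure D3:**
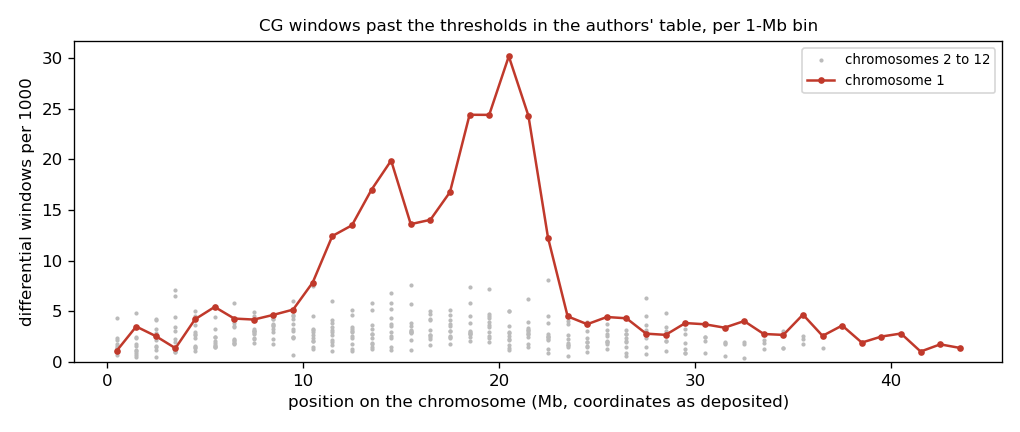
Each point is a bin of 1000000 bp, placed by its position on its chromosome in Mb and by the number of CG windows past the thresholds per 1000 windows of the authors' deposited table. Chromosome 1 (red line) reached 30.2 per 1000, and bins of the other chromosomes (gray) stayed at or below 8.12.

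Windows at 24-nt PHAS loci were more often differential than windows at shifted positions of the same loci. The shifts did not match the number of windows, their methylation level or their coverage, so the excesses are not adjusted for these. Their p concerns where loci lie along the chromosomes and does not measure variation between libraries. At the 31585 loci found in all 3 libraries of either genotype, 2% of the CHH windows in the authors' deposited table passed the thresholds, 3.35-fold the mean of 1000 circular shifts (two-sided permutation p = 0.002, the smallest they can give, adjusted p = 0.004). The excess in the authors' deposited table was 2.72-fold for CHG and 1.38-fold for CG (permutation p = 0.002, adjusted p = 0.004 for each). The mean CHH difference of the authors' deposited table at these loci was 0.70 points, against 0.19 elsewhere. Most 24-nt loci scored low, with medians of 0.2 to 0.4 per library, and strong loci differed. At the 143 loci in all 6 libraries that reached a score of 25, this mean was -0.54 points (permutation p = 0.002, not adjusted). At the 70 loci that reached 25 with every mutant score above every wild-type score, it was 0.46 points. At 241 loci of the 21-nt class, CHH windows of the authors' deposited table were differential 2.16 times as often as at shifted positions (permutation p = 0.006, adjusted p = 0.009). The share of differential windows at 21-nt loci did not pass for CG (1.39-fold, permutation p = 0.44) or CHG (0.98-fold, permutation p = 0.847) of the authors' deposited table. The mean CHG difference of the authors' deposited table at these loci did pass, at -0.11 points against a mean of 0.33 at shifted positions (permutation p = 0.016, adjusted p = 0.024). With 21-nt loci of any library this was lost, at 0.33 points of the authors' deposited table against 0.31 (permutation p = 0.751).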

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

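Tests chosen after the data were seen were limma voom on recovered fragments, the thresholds on phase score and the lists with both left-out pairs kept; the others were planned. Depth limits low genes most, and the depth behind the loci and windows was not given in the sources used here. Of 13 named genes called in limma, *AGO18*, LOC_Os12g14310 and LOC_Os12g39470 kept their calls in all 12 alternatives. *SDS* and *ZEP1* kept theirs in 11, losing them without a filter on low values (adjusted p over all alternatives 0.0022 to 0.0512 and 0.00357 to 0.0593). *OsRDR6* passed in none of 12 (log2 fold change 0.49 to 0.60, limma adjusted p 0.0554 to 0.248). Over the 40 named genes, 422 values kept direction and side of the threshold, 46 lost and 6 gained the call. All 46 losses fell on the 13 called genes, which had 11 or 12 alternatives each. Many of the 422 values are of genes that were not called to begin with, so they say little about how stable the calls are. List medians kept both in 125 values, lost the call in 3, all for the late tapetum and pollen wall, and gained it in 1.

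Without a filter on low values, where more genes entered both the fit and the adjustment, 17 genes rose and 85 fell. With a minimum log2 fold change of 1 they were 157 and 251. Leaving out 1 library, where a lone library is assumed to vary like the other genotype's pair, gave 95 to 195 higher and 183 to 307 lower genes, and 4 to 5 lists past camera. Of 5 lists past camera, 0 passed with an estimated correlation and 2 (DSB formation and tasiR-ARF targets) with fry. The estimated correlation was 0.798 for photosynthesis genes and ran from -0.239 to -0.019 for the other lists past camera. For those others the lost call does not show that members varied together. With both left-out pairs kept, 6 lists passed camera. With voom, 237 genes rose and 377 fell, and 564 of these calls were shared with limma on FPKM. Leaving out 1 library turned list medians for the anther wall (-0.079 and -0.032, range -0.079 to 0.17) and stamen identity (-0.068, range -0.068 to 0.384). It also turned the fold changes of *PAIR1* (-0.179 and -0.034, range -0.179 to 0.331), *MTOPVIB* (-0.01, range -0.01 to 0.251) and *MADS2* (-0.102 and -0.004, range -0.102 to 0.384), none of them called; the cause was not tested.

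Replicate numbers were not shown to pair the samples. Deviations of same-numbered mRNA libraries correlated at 0.147 with only 2 pairs, and those of small RNA libraries at 0.199, -0.068 and 0.053 (21-nt) and 0.047, 0.044 and 0.057 (24-nt), where each 24-nt library correlated best with its own number. With the replicate block, 391 genes rose and 485 fell, *CRC1*, *ARF15* and *MADS1* gained calls, and *OsRDR6* stayed at 0.553 (limma adjusted p = 0.0556). In the replicate block the exact sign-flip p was 0.25, the smallest possible for 3 pairs, for the differences in loci per library (-87.7 and 23943) and in median score (-250.6 and 0.8). No paired analysis was possible for methylation because the authors' deposited table holds no values per library.

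For 21-nt loci, leaving out 1 library gave differences in number of -153 to -42.5 and in median score of -225 to -142, sets of 100 to 189 wild-type and 52 to 106 mutant loci. At a score of at least 25 the mutant set held 17 loci, and over all loci of each library the median score differed by 0.033, turning direction. For 24-nt loci, leaving out 1 library gave differences of 17798 to 28831 and of 0.617 to 0.9, and sets of 650 to 1011 and 4706 to 9728 loci. The 24-nt difference in number was 148 at a score of at least 10 and turned to -94, -80 and -53.3 at scores of at least 25, 50 and 100. With sets built anew from the stronger part of all loci, 213 loci were found only in wild type and 4246 only in the mutant. Built anew from loci with a score of at least 25, the sets held 113 and 12. The cause was not tested.

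Counts of windows in the authors' deposited table moved with the limits, by their construction, and positive windows outnumbered negative ones under each. At q below 0.001 the authors' deposited table gave 3363 positive and 2802 negative CG, 1356 and 1074 CHG, and 19619 and 6891 CHH windows. At 10 points it gave 12184 and 8997 CG and 6106 and 4173 CHG windows, and at q below 0.05, 4843 and 3785 CHG windows. At 40 points (25 for CHH) it gave 1834 and 1629 CG, 774 and 627 CHG, and 1683 and 774 CHH windows. Non-overlapping windows of the authors' deposited table numbered 2725 and 2270 for CG, 1357 and 1073 for CHG and 7395 and 2632 for CHH, and merged CHH regions 15897 and 6309. The CHG ratio at 21-nt loci, below 1 in the report, was 1.23 with loci in any library and 1.04 at an overlap of 50 bp; the cause was not tested. A limit on coverage was not run.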

Other observations

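All tests in this part were chosen after the result was seen except that on CHH windows in the chromosome 1 stretch. Genes lower in the mutant stood side by side more often than chance order gives. Of the 389 lower genes, 81 pairs of neighboring identifiers were both lower, against a mean of 7.34 and a highest value of 14 in 1000 shuffles. There were 19 runs of 3 or more such genes, the longest of 6. The 78 genes in these runs kept a median of 0.196 of their wild-type FPKM, and 2 of them kept less than 0.05. For higher genes there were 18 such pairs, against a mean of 3.09 in shuffles. Leaving out 1 library left 52 to 68 lower pairs, and dropping the filter on low values left 13.

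For the PHAS loci that part the genotypes, the real split of the 6 libraries gave 144 loci of the 21-nt class, and the highest of the other splits gave 12. For 24-nt loci the real split gave 4451 and the highest other 2100. In each class 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. At the 51 loci of the 21-nt class found only in mutant libraries, the authors' deposited table had mean differences of -1.35 points for CHG and -0.52 for CHH (permutation p = 0.002 for each, not adjusted) and of -0.20 for CG (permutation p = 0.226). At the 93 loci found only in wild-type libraries no context of the authors' deposited table passed (lowest permutation p = 0.106, for CHG).

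More 24-nt loci with fewer strong ones is the first pattern weighed. Deeper mutant libraries as its whole cause are argued against by the strong loci, provided that the authors' score grows with reads. Their number at a score of at least 25 was 0.479 of the wild-type number, with every mutant library below every wild-type library. At a score of at least 10 the genotypes overlapped. The fewer strong loci are part of the pattern itself, and whether depth made the rise in total number was not tested. A candidate explanation that stays open is that strong loci took fewer reads and left more for weak ones, since the median score at shared loci was higher in the mutant (2.85 as a ratio, whose size means little for a score of unknown definition) and library totals were not given in the sources used here. The authors' deposited table adds a hypothesis on its sign. At the 147 strong loci lower in every mutant library the mean CHH difference was -2.45 points (shifted positions 0.04 to 0.53). The 0.46 at the 70 strong loci higher in every mutant library lay above the mean of its shifted positions, 0.24 (0.05 to 0.51, permutation p = 0.004, not adjusted). It lay below the 0.70 of all 24-nt loci, and so does not set these 70 apart from 24-nt loci at large. At the 381 loci of the 24-nt class found only in wild type, the mean in the authors' deposited table was -0.25 (shifted positions 0.05 to 0.43). Of these 381 loci, 45 reached a score of 25, with a mean of -2.16 in the authors' deposited table, and they are also among the 147. The -0.25 is therefore no separate support, and the weaker loci found only in wild type were not tested alone. At the 4070 loci found only in mutant libraries the mean was 0.67, near the 0.70 of all 24-nt loci. The -2.45 goes with positive values standing for more methylation in the mutant, if 24-nt small RNAs guide CHH methylation at these loci. At the 23 strong 21-nt loci higher in every mutant library the mean went the other way, at -0.60 (permutation p = 0.006, not adjusted).

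The gathering of differential CG windows on chromosome 1 is the second pattern. The stretch held 16.1% of differential CG windows but 2.73% of CG windows in the authors' deposited table, 6.83 times the rate elsewhere, with 865 positive and 749 negative, and the excess was 4.64-fold for CHG and 0.88-fold for CHH. Few usable windows near the centromere are argued against, since 265 bins of other chromosomes with no more windows had a median of 2.81 and a highest value of 7.60 per 1000 in the authors' deposited table, below the median of 16.9 in the stretch. A hypothesis that stays open is a stretch linked to the mutated gene that differs between the genotypes. The identifier of *OsRDR6* stands at 43.4% of the chromosome 1 identifiers, and the stretch covers 25.4% to 53.2% of the chromosome's length. This check cannot decide, because many genes would pass it in so wide a stretch, chosen after the values were seen. It also sets order among identifiers against length, and genes need not be evenly spaced. Sequence variants read as methylation differences cannot be told apart from this hypothesis. CHH windows of at least 25 points in the authors' deposited table showed a 1.03-fold rate there, and a window with many CHH cytosines could hide 1 variant. Genes at the same share of identifiers were called at 2.63%, against 3.17% elsewhere (Fisher's exact two-sided p = 0.683), but these need not be the genes of the stretch.

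Genes lower in the mutant, beside floret genes with higher values, are the third pattern. More floret tissue around the mutant anthers as the whole cause of the falls would lower genes of meiotic cells together. The 21 genes of the 3 meiotic lists had a median of -0.19 (quartiles -0.40 and 0.12). The called lower genes had a median of -1.27, but they were selected for their falls. The comparison therefore cannot decide, and this explanation stays open. For the rises in photosynthesis genes and in genes of palea, lemma, lodicule and carpel identity it stays open too. Between wild-type replicates (2 minus 1) the first list differed by a median of -1.11. The second differed by -0.48, just short of the bound of -0.5 set for both. Mutant anthers at an earlier stage may also lie behind the lower genes, and *AM1*, *MEL1* and *MEL2*, genes of meiotic entry, had a median of 0.82. With no series of stages, the stage and a direct effect of the mutation cannot be told apart, and the effect of the genotype itself stays untested beside them.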
